A study of Mus musculus with 12 samples.

How the data were processed

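KPC cells are mouse pancreatic cancer cells. Per the labels, they were grown in DMEM with fetal bovine serum and left as controls or treated with 1 of 3 compounds, JQ1, I-BET151 or ITF2357, at 1 µM for 48 h. Each of the 4 groups had 3 libraries, 12 in all. The labels describe the control both as untreated and as receiving PBS, and no solvent of the compounds is named in the sources used here. Per the labels' protocols, total RNA was taken with TRIzol and a miRNeasy column, libraries were made with the KAPA RNA HyperPrep kit, and paired ends were read on an Illumina NovaSeq instrument. Whether poly-A RNA was selected or ribosomal RNA was depleted, and whether the counting used the strand, is not given in the sources used here. Without strand, counts of a gene and of a gene overlapping it on the opposite strand cannot be told apart. Counts of near-identical paralogs are likewise uncertain.

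Per the submitters' processing notes, bcl2fastq, STAR 2.7.2a, featureCounts of Subread 2.0.1 and edgeR 3.38.4 were used with genome build mm10. The annotation release is not given in the sources used here. The gene identifiers of 17165 of the 17340 genes (99.0%) matched GENCODE M21 exactly, version included, and coordinates are from that annotation (build mm10, counted from 1). The authors deposited 1 table with raw counts per gene and library, which the analysis used. It also holds the authors' log2 CPM and log2 RPKM per library, the authors' log2 fold changes of each compound against the control, and the authors' p-values with false discovery rates. Judged from its values, the deposited log2 CPM was relative to library totals times a scaling factor per library, and the RPKM values differ from the CPM values only by the gene length. The deposited log2 values were used only to check the match of columns to libraries. The rule by which genes were kept in the table is not given in the sources used here, and the lowest total of a gene over all libraries was 51 counts.

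Library totals ranged from 21 to 31.2 M counts. The biological coefficient of variation common to all genes was 3.37%. At this depth and spread, the quasi-likelihood test was tested on simulated counts with 200 changed genes among 17340 in each comparison against control. For JQ1 against control it recovered 68% of the genes changed 1.25-fold, 74% of those changed 1.5-fold, 92% of those changed 2-fold and 100% of those changed 4-fold. For I-BET151 against control the shares were 60%, 82%, 96% and 100%, and for ITF2357 against control 64%, 74%, 90% and 98%. False calls made up 4.3%, 3.8% and 4.4% of all calls in these 3 comparisons, which shared 1 set of simulated counts. A gene list planted in each compound was found, and 2 of the other lists were also called in the simulated JQ1 comparison. The changed genes were drawn from genes above a floor of mean expression, so the recovered shares do not cover genes below it. Far fewer genes were changed than are called in the data, so scaling under such broad change was not tested. Bounds for a gene with no count in a group were set against a floor of 3 counts over the group and cover counting error only.

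Counts were analysed in R 4.3.3 with edgeR 4.0.16. The filter filterByExpr removed 0 genes, library sizes were scaled with TMM factors, and all 12 libraries entered 1 quasi-likelihood fit without covariates. The 6 comparisons were each compound against the control and each compound against the others. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all 17340 genes. Fold changes are the fitted log2 fold changes of edgeR with standard errors of the fit. Correlations and principal components used log2 CPM with a prior count of 2. CPM values are counts per M library counts, scaled with the TMM factors, given as mean ± SD of 3 libraries. Standard errors of log2 fold changes follow a ± sign and are marked SE.

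The groups, the 6 comparisons, the test, the alternatives, 28 gene lists and the rule for naming genes were chosen before the data were examined. The rule took, per comparison, the 7 largest rises and the 7 largest falls among changed genes with a mean log2 CPM of at least 2 whose libraries did not overlap between the groups. It also took from each list up to 3 changed members and the largest opposite change, and 14 genes in every comparison, among them Hexim1, Serpini1, Myc, Brd2, Cd274, Tnfrsf14, Cdkn1a, H1f0, Cdh1, Vim, B2m, Hmox1 and Ccl2. Tnfrsf14 was not analysed here, and some genes that the rule took are not reported here. The lists held genes of known pathways, epithelial and mesenchymal markers, pancreatic ductal and acinar genes, and markers of fibroblasts, macrophages and leukocytes, and endothelium. Lists with at least 4 measured genes, 25 of the 28, were tested against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists and comparisons. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move one way on balance and compares them with no other genes.

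Alternatives were the edgeR likelihood ratio test, DESeq2 1.42.0, other scalings (RLE, upper quartile and library totals), a stricter filter (5 CPM in at least 3 libraries), only the 2 groups compared, replicate number as a block, each library left out in turn, an adjusted p under 0.01 and a change of at least 2-fold. A fit to protein-coding genes only was chosen after seeing the data. Overlaps between comparisons that share the controls were set beside the overlap of independent lists and beside 20 simulations of unchanged groups. In these, the counts of all 12 libraries, the controls included, were drawn from the control means with independent noise.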

Results

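Gene expression was measured by RNA-seq in KPC cells, a mouse pancreatic cancer line, after 48 h with 1 µM of a BET bromodomain inhibitor (JQ1 or I-BET151) or of the histone deacetylase inhibitor ITF2357 (givinostat), and in control cells. BET proteins bind acetylated histones at active genes, and histone deacetylases remove that acetylation. JQ1 is a thienotriazolodiazepine and I-BET151 a quinoline-based dimethylisoxazole, so the BET inhibitors differ in structure at a matched dose and time. The 12 libraries formed 4 groups of 3, and 17340 genes had counts. Totals ranged from 21.9 to 23.2 M counts in control, 21 to 29.1 M in JQ1, 22.2 to 25.6 M in I-BET151 and 23.2 to 31.2 M in ITF2357 libraries. Libraries of a group correlated with r from 0.9893 to 0.9939 across genes, which are not independent replicates. Counts of each pair of replicates differed by more than sampling noise, with a chi-square per degree of freedom from 1.63 to 5.31. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

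**Figure D1:**
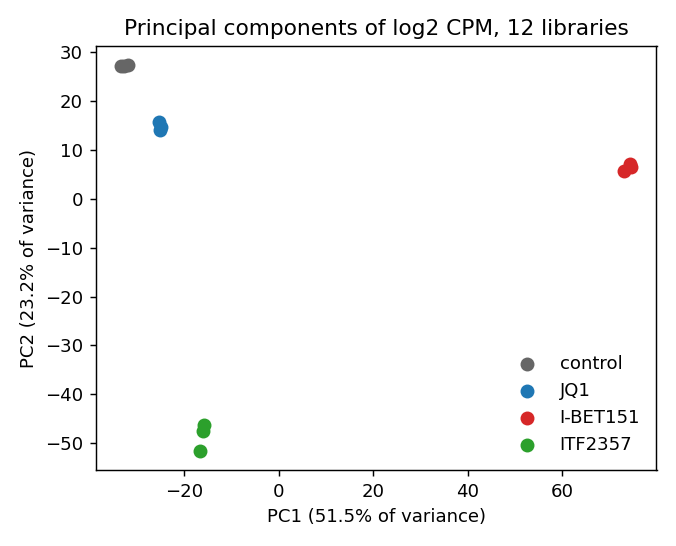
Principal components of log2 CPM over the 12 libraries, with component 1 (51.5% of variance) on the x axis and component 2 (23.2%) on the y axis and 1 point per library, coloured by group. I-BET151 libraries lay between 73.05 and 74.56 on component 1, JQ1 libraries between -25.33 and -25.02 and control libraries between -33.34 and -31.97.

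Each compound changed the expression of many genes. I-BET151 changed 10945 genes against control, 5297 higher and 5648 lower, and 2729 of them by at least 2-fold. ITF2357 changed 9356 genes, 4785 higher and 4571 lower, with 1501 at least 2-fold. JQ1 changed 4308 genes, 2176 higher and 2132 lower, and 105 of them by at least 2-fold. The median size of a change among changed genes was 0.23 on the log2 scale with JQ1, 0.55 with I-BET151 and 0.42 with ITF2357. The values the authors deposited had 4326, 11094 and 9531 genes that passed the same threshold for JQ1, I-BET151 and ITF2357, and 4176, 10867 and 9260 of these were also called here. Rises made up 48.4% of the I-BET151 calls with TMM factors and 33% with library totals, which moved the median log2 fold change of all genes by -0.16. The median of every list reported below as changed against control lay further from 0 than the largest shift of this kind in its comparison. All scalings used are relative to the counts of a library, so a change in total RNA per cell cannot be seen.

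**Figure D2:**
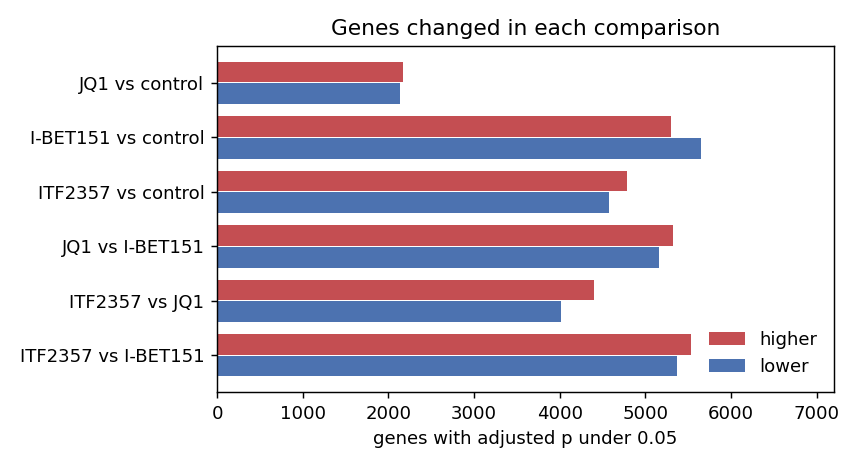
Number of genes with an edgeR adjusted p under 0.05 (x axis) in each of the 6 comparisons (y axis), with red bars for genes higher and blue bars for genes lower in the first-named group. JQ1 against control gave 4308 changed genes and I-BET151 against control 10945.

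Of 25 gene lists tested with camera, 13 passed with JQ1, 15 with I-BET151 and 14 with ITF2357 against control. With an estimated correlation 8, 11 and 8 of them held. These were the cytokine, MYC, mitosis, mesenchymal, extracellular matrix, stress response, cholesterol and glycolysis lists for JQ1. For I-BET151 the same lists held, and the DNA replication, histone and NRF2 lists with them. The MYC and stress response lists fell with both BET inhibitors, whereas the cytokine, mitosis, mesenchymal, extracellular matrix, cholesterol and glycolysis lists rose with JQ1 and fell with I-BET151. For ITF2357 they were the DNA replication, mitosis, epithelial, histone, NRF2, stress response, cholesterol and RAS-MAPK lists. Median, mean and test had the same sign in each list past the camera threshold. They differed in sign in lists that did not pass, among them MHC class I with JQ1 (median -0.01, mean -0.09, test upward) and with I-BET151 (median -0.04, mean -0.38, test upward), and the neuronal list with I-BET151 (median 0.10, mean -0.06, test upward). The same held for the extracellular matrix list with ITF2357 (median -0.03, mean -0.03, test upward).

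**Figure D3:**
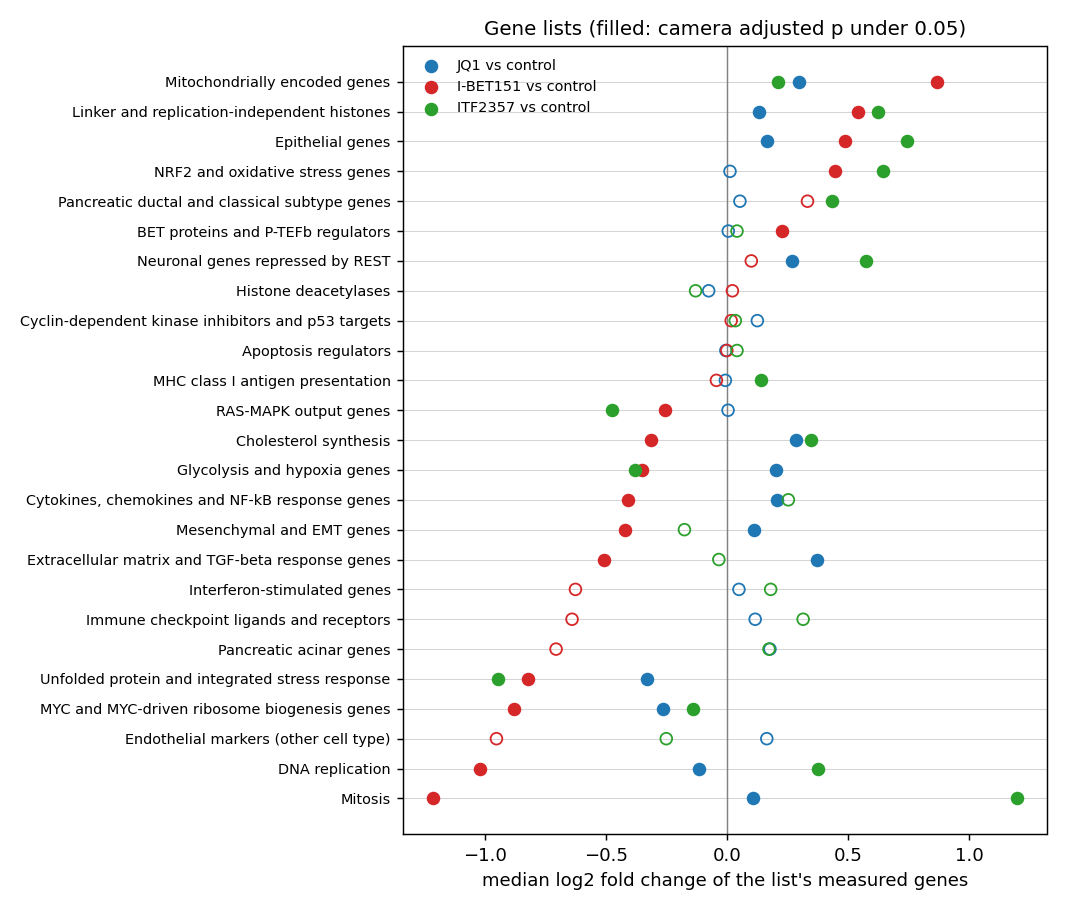
Median log2 fold change against control (x axis) of the measured genes of each of 25 gene lists (y axis), with 1 point per compound, filled where the camera adjusted p was under 0.05. The mitosis list lay at 1.20 with ITF2357, -1.22 with I-BET151 and 0.11 with JQ1, and the stress response list lay below 0 with each compound.

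JQ1 against control asked what this BET inhibitor changes in pancreatic cancer cells. Most changes were small: ribosome biogenesis and stress response genes fell, and cholesterol synthesis, extracellular matrix, hypoxia and cytokine genes rose. Btg2, an antiproliferative gene, rose from 28.2 ± 1.27 CPM in control to 56.3 ± 0.743 CPM (SD, n = 3), a log2 fold change of 1.00 ± 0.05 SE (edgeR adjusted p = 1.80e-17). Other large rises were those of Pamr1 (1.23 ± 0.17 SE), Ddit4l (0.97 ± 0.10 SE), Rasl11a (0.97 ± 0.16 SE), Zfp36, an mRNA decay factor (0.94 ± 0.05 SE), Cebpd (0.89 ± 0.08 SE) and Adamts1 (0.89 ± 0.09 SE). Cdsn, which encodes corneodesmosin, fell from 26.9 ± 0.737 to 9.54 ± 0.976 CPM (SD, n = 3), a log2 fold change of -1.50 ± 0.09 SE (edgeR adjusted p = 5.92e-15). Bcat1, a branched-chain amino acid transaminase, changed by -1.11 ± 0.13 SE, Avil by -1.10 ± 0.08 SE and Cmss1 by -1.04 ± 0.11 SE. The log2 fold change of Nnat, JQ1 vs control, was -1.16 ± 0.26 SE (edgeR adjusted p = 0.000872, DESeq2 adjusted p = 0.0742).

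Myc, at 61985391 to 61990374 on the + strand of chromosome 15 (ENSMUSG00000022346.15), fell with JQ1 from 393 ± 8.65 to 316 ± 3.75 CPM (SD, n = 3), a log2 fold change of -0.32 ± 0.03 SE (edgeR adjusted p = 1.34e-11). In the list of MYC and ribosome biogenesis genes 30 of 37 measured genes fell, 1 rose and 6 did not pass (31 and 2 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 1.36e-20). Rrp9 changed by -0.58 ± 0.09 SE and Srm, spermidine synthase, by -0.49 ± 0.07 SE, whereas Mycn rose by 0.64 ± 0.17 SE. In the unfolded protein and integrated stress response list 15 of 24 fell, 2 rose and 7 did not pass (15 and 3 adjusted over the list alone; camera adjusted p = 8.89e-10). Its largest falls were those of the transcription factor gene Ddit3 (from 28.2 ± 2.44 to 14.1 ± 0.552 CPM), Trib3 (-0.94 ± 0.06 SE) and Ppp1r15a (-0.79 ± 0.06 SE), and Ddit4 rose by 0.28 ± 0.04 SE. Slc7a11, the cystine transporter gene of the NRF2 list, changed by -0.71 ± 0.04 SE. The NRF2 list as a whole did not pass, with 9 of 25 genes higher and 4 lower (camera adjusted p = 0.203).

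Cholesterol synthesis genes moved almost as one with JQ1: 22 of 25 rose, 0 fell and 3 did not pass (23 and 0 adjusted over the list alone; camera adjusted p = 2.55e-17), with Idi1 at 0.58 ± 0.07 SE, Nsdhl at 0.46 ± 0.05 SE and Hmgcs1 at 0.45 ± 0.03 SE. In the extracellular matrix and TGF-beta list 16 of 24 rose, 3 fell and 5 did not pass (camera adjusted p = 1.27e-11). Col12a1 rose by 0.69 ± 0.05 SE and Thbs1, thrombospondin, by 0.67 ± 0.02 SE, while Inhba changed by -0.27 ± 0.04 SE. Of the mesenchymal genes 11 of 22 rose, 2 fell and 9 did not pass (camera adjusted p = 0.000672), with S100a4 at 0.53 ± 0.08 SE and Snai2, an EMT transcription factor gene, at -0.67 ± 0.06 SE. Of the glycolysis and hypoxia genes 19 of 27 rose, 3 fell and 5 did not pass (camera adjusted p = 2.66e-09), with Bnip3 at 0.80 ± 0.05 SE, Egln3 at 0.58 ± 0.05 SE and Vegfa at -0.28 ± 0.02 SE. Cytokine and NF-kB response genes rose in 14 of 25 cases, fell in 4 and did not pass in 7 (camera adjusted p = 0.000516), and the neutrophil chemokine genes Cxcl5 and Cxcl1 rose by 0.78 ± 0.04 SE and 0.72 ± 0.07 SE. Mitosis genes rose in 12 of 33 cases, with 0 lower and 21 not past the test (camera adjusted p = 0.00113).

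Several list calls for JQ1 were lost with an estimated correlation. Epithelial genes rose in 8 of 21 cases and fell in 1, with Cdh1, E-cadherin, at 0.27 ± 0.02 SE (camera adjusted p = 0.000171, and adjusted p = 0.0506 with an estimated correlation). DNA replication genes fell in 7 of 36 cases and rose in 2 (camera adjusted p = 0.0368, and adjusted p = 0.0866 with an estimated correlation). REST-repressed neuronal genes rose in 6 of 13 cases, with Map2 at 0.66 ± 0.07 SE (camera adjusted p = 0.00149, and adjusted p = 0.0673 with an estimated correlation). The histone list, which holds linker histones, variants and genes of the histone clusters, had 6 of 15 genes higher and 1 lower (camera adjusted p = 0.0114, and adjusted p = 0.0543 with an estimated correlation). Mitochondrially encoded genes rose in 11 of 13 cases (camera adjusted p = 1.47e-12, and adjusted p = 0.0713 with an estimated correlation). Their share of all counts was 2.27% ± 0.05 in control and 2.73% ± 0.03 in JQ1 libraries (SD, n = 3).

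Among single genes followed in each comparison, Serpini1 rose with JQ1 by 0.67 ± 0.11 SE (edgeR adjusted p = 1.18e-05). Hexim1, which encodes an inhibitor of the elongation kinase P-TEFb and is a known responder to BET inhibition, went from 16.8 ± 1.05 to 20 ± 1.02 CPM (SD, n = 3), a log2 fold change of 0.25 ± 0.07 SE (edgeR adjusted p = 0.0121). The call on the log2 fold change of Hexim1, JQ1 vs control, was lost without control replicate 3 (edgeR adjusted p = 0.0920) and without JQ1 replicate 2 (edgeR adjusted p = 0.0640). The log2 fold change of Brd2, JQ1 vs control, was 0.08 ± 0.03 SE (edgeR adjusted p = 0.0363), a call lost when any of 4 libraries was left out, control replicate 1 or 3 or JQ1 replicate 2 or 3 (edgeR adjusted p from 0.109 to 0.155). Cd274, which encodes the checkpoint ligand PD-L1, rose from 5.50 ± 0.371 to 7.96 ± 0.293 CPM (SD, n = 3; edgeR adjusted p = 0.00174). B2m rose by 0.21 ± 0.03 SE, H1f0 by 0.18 ± 0.03 SE and Vim by 0.08 ± 0.02 SE, and Hmox1 changed by -0.30 ± 0.06 SE. The log2 fold change of Ccl2, JQ1 vs control, was 0.38 ± 0.12 SE (edgeR adjusted p = 0.0224), a call lost without control replicate 1 (edgeR adjusted p = 0.226), JQ1 replicate 1 (0.0722) or JQ1 replicate 2 (0.0626). Cdkn1a (-0.23 ± 0.10 SE, edgeR adjusted p = 0.0855) did not pass.

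The other lists did not pass with JQ1. RAS-MAPK output genes were divided, with 8 of 26 higher and 8 lower (camera adjusted p = 0.881), as were apoptosis regulators with 6 of 24 higher and 4 lower (camera adjusted p = 0.706). Interferon-stimulated genes (5 of 27 higher, 0 lower; camera adjusted p = 0.421), checkpoint genes (5 of 18 higher, 3 lower; camera adjusted p = 0.341) and MHC class I genes (5 of 17 higher, 3 lower; camera adjusted p = 0.304) did not pass. Nor did the BET and P-TEFb list (4 of 13 higher, 1 lower; camera adjusted p = 0.425), the histone deacetylases (1 of 15 higher, 3 lower; camera adjusted p = 0.354) or the list of cyclin-dependent kinase inhibitors and p53 targets (6 of 17 higher, 2 lower; camera adjusted p = 0.112). Of the acinar genes 1 of 4 was lower, and of the fibroblast, endothelial, macrophage and MHC class II genes 0 changed.

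I-BET151 against control asked the same of the other BET inhibitor. Lists of proliferation, ribosome biogenesis, mesenchymal, matrix and cytokine genes fell, and the histone and NRF2 lists rose. Hexim1, at 103116231 to 103119725 on the + strand of chromosome 11 (ENSMUSG00000048878.6), rose from 16.8 ± 1.05 to 59.6 ± 4.51 CPM (SD, n = 3), or 3.55-fold (edgeR adjusted p = 2.24e-22). Myc fell from 393 ± 8.65 to 133 ± 4.58 CPM, a log2 fold change of -1.56 ± 0.03 SE (edgeR adjusted p = 3.02e-31). The largest rise was that of Clca1, a goblet cell secretory gene at 145003817 to 145032776 on the - strand of chromosome 3, from 2.42 ± 0.549 to 186 ± 1.96 CPM (77.2-fold; edgeR adjusted p = 1.54e-35). The collagenase gene Mmp13, at 7272514 to 7283331 on the + strand of chromosome 9, went from 67.3 ± 0.350 to 0.721 ± 0.266 CPM (92.0-fold lower; edgeR adjusted p = 3.33e-31).

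The other largest rises with I-BET151 were those of Depp1 (4.11 ± 0.11 SE), the mucin gene Muc1 (3.43 ± 0.03 SE, from 70.3 ± 0.804 to 755 ± 22.3 CPM), Pamr1 (2.92 ± 0.15 SE), Sptssb (2.82 ± 0.10 SE), Casz1 (2.68 ± 0.09 SE) and Mcf2l (2.67 ± 0.15 SE). The other largest falls were those of Bcat1 (-6.16 ± 0.24 SE), Bcl2l15 (-6.03 ± 0.17 SE), Ndst3 (-5.98 ± 0.21 SE), the stromelysin gene Mmp10 (-5.93 ± 0.23 SE) and Mrc1 (-5.83 ± 0.09 SE). Prl2c2, a proliferin gene with near-identical paralogs whose counts are therefore uncertain, had 0 counts in each I-BET151 library and 651 over the 3 control libraries. Against a floor of 3 counts over the group it was at least 205-fold lower.

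**Figure D4:**
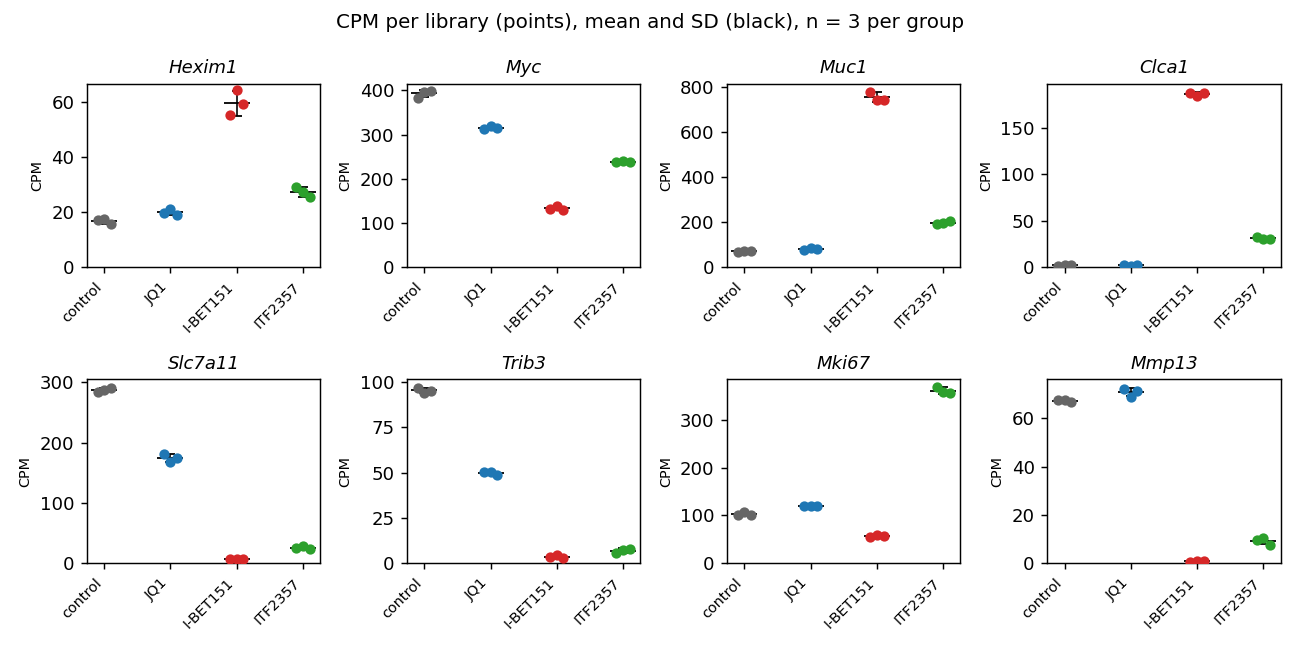
CPM (y axis, linear scale, TMM-scaled) of 8 genes in the libraries of each group (x axis), with 1 point per library and the mean and SD of 3 libraries in black. Hexim1, Muc1 and Clca1 were highest and Slc7a11, Trib3, Mmp13 and Myc lowest in I-BET151 libraries, and Mki67 was highest in ITF2357 libraries at 362 CPM.

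Cell cycle genes fell together with I-BET151. All 33 measured mitosis genes fell (median -1.22; camera adjusted p = 4.17e-16), among them Mybl2 (-2.00 ± 0.13 SE), Tpx2 (-1.95 ± 0.05 SE) and Aurka (-1.87 ± 0.09 SE). Of the DNA replication genes 35 of 36 fell and 1 did not pass (median -1.02; camera adjusted p = 4.01e-14), with the origin licensing gene Cdt1 at -2.38 ± 0.08 SE, Cdc45 at -2.25 ± 0.11 SE and Tk1 at -2.02 ± 0.08 SE. MYC and ribosome biogenesis genes fell in 34 of 37 cases, with 2 higher (camera adjusted p = 1.48e-13). Mycl changed by -3.54 ± 0.23 SE and Mycn rose by 1.48 ± 0.16 SE. The list of cyclin-dependent kinase inhibitors and p53 targets was divided, with 7 of 17 genes higher and 7 lower (camera adjusted p = 0.718). Btg2 rose by 2.31 ± 0.04 SE, and Cdkn1a, the p21 gene, went from 15.6 ± 1.33 to 10.9 ± 0.574 CPM (-0.51 ± 0.10 SE; edgeR adjusted p = 3.21e-05). Apoptosis regulators were divided too, with 8 of 24 higher and 9 lower (camera adjusted p = 0.749). The pro-apoptotic gene Bmf rose by 1.62 ± 0.04 SE and the anti-apoptotic gene Mcl1 rose 2.05-fold.

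Mesenchymal genes fell in 16 of 22 cases with I-BET151, rose in 3 and did not pass in 3 (camera adjusted p = 3.07e-05). Mmp3 changed by -4.82 ± 0.18 SE, and the transcription factor genes Prrx1 and Snai1 by -3.37 ± 0.28 SE and -2.80 ± 0.26 SE. Vim fell from 1449 to 1053 CPM (edgeR adjusted p = 7.09e-20). Extracellular matrix and TGF-beta genes fell in 17 of 24 cases, rose in 6 and did not pass in 1 (camera adjusted p = 0.00171), with Col6a2 at -3.55 ± 0.10 SE and Ltbp2 at -3.22 ± 0.13 SE, while Loxl2 rose by 0.91 ± 0.04 SE. Beside these groups, the 3 measured fibroblast markers were also lower: Col1a1 (-1.90 ± 0.11 SE), Pdgfra (-1.50 ± 0.18 SE) and Pdgfrb (-0.69 ± 0.27 SE; edgeR adjusted p = 0.0255). The call on the log2 fold change of Pdgfrb, I-BET151 vs control, was lost without control replicate 1 (edgeR adjusted p = 0.0776), control replicate 2 (0.0615), I-BET151 replicate 2 (0.0688) or I-BET151 replicate 3 (0.105). Cytokine and NF-kB response genes fell in 17 of 25 cases and rose in 4 (camera adjusted p = 0.00121), led by Il1rn, the interleukin-1 receptor antagonist (-4.39 ± 0.05 SE), Csf2 (-3.36 ± 0.28 SE) and Ptgs2, cyclooxygenase 2 (-2.82 ± 0.04 SE). Il18 rose by 2.50 ± 0.13 SE and Ccl2 changed by -2.08 ± 0.17 SE.

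RAS-MAPK output genes fell in 17 of 26 cases with I-BET151 and rose in 7 (camera adjusted p = 0.00172, and adjusted p = 0.0709 with an estimated correlation). The EGFR ligand gene Areg changed by -4.19 ± 0.09 SE and the AP-1 gene Fosl1 by -3.52 ± 0.06 SE, whereas Fos rose by 2.01 ± 0.06 SE. Glycolysis and hypoxia genes fell in 19 of 27 cases and rose in 4 (camera adjusted p = 0.000425), with the lactate transporter gene Slc16a3 at -2.60 ± 0.07 SE and Hk2 at -1.39 ± 0.04 SE. Cholesterol synthesis genes fell in 19 of 25 cases and rose in 4 (camera adjusted p = 0.00101), with Cyp51 at -0.76 ± 0.04 SE and Insig1 at 0.73 ± 0.03 SE. Stress response genes fell in 14 of 24 cases, rose in 8 and did not pass in 2 (camera adjusted p = 0.000552). Trib3 went from 95.4 ± 1.42 to 3.45 ± 0.705 CPM, and Chac1 and Psat1 changed by -3.37 ± 0.10 SE and -2.66 ± 0.03 SE, while Sdf2l1 rose by 0.92 ± 0.13 SE.

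NRF2 and oxidative stress genes rose in 18 of 25 cases with I-BET151, fell in 6 and did not pass in 1 (camera adjusted p = 1.21e-05). The glutathione genes Gsta4 (2.59 ± 0.03 SE) and Gclc (2.09 ± 0.04 SE) rose, whereas Slc7a11, at 49892526 to 50443614 on the - strand of chromosome 3, went from 287 ± 3.40 to 6.55 ± 0.526 CPM (-5.46 ± 0.06 SE; edgeR adjusted p = 1.09e-36). Genes of the histone list rose in 11 of 15 cases and fell in 1 (camera adjusted p = 0.000168), with Hist3h2a at 2.46 ± 0.14 SE and H1f0 at 1.00 ± 0.03 SE; counts of such histone paralogs may be split. Genes of the BET and P-TEFb list rose in 9 of 13 cases and fell in 3, with Brd2 at 1.16 ± 0.03 SE (camera adjusted p = 0.0331, and adjusted p = 0.127 with an estimated correlation). Serpini1, which encodes a serpin and neither a BET protein nor a P-TEFb regulator, rose by 1.75 ± 0.10 SE. Epithelial genes rose in 12 of 21 cases and fell in 4 (camera adjusted p = 0.000241, and adjusted p = 0.0543 with an estimated correlation), with Elf3 at 1.67 ± 0.07 SE and Cdh1 at 0.94 ± 0.02 SE. The 13 mitochondrially encoded genes rose (camera adjusted p = 1.19e-08, and adjusted p = 0.132 with an estimated correlation), and their share of counts was 3.88% ± 0.07. The nuclear RNA Malat1 took 7.26% ± 0.13 of counts in I-BET151 and 2.65% ± 0.04 in control libraries (SD, n = 3).

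The interferon, checkpoint and MHC class I lists did not pass with I-BET151. Interferon-stimulated genes fell in 12 of 27 cases and rose in 5 (camera adjusted p = 0.219), with Xaf1 at -2.16 ± 0.22 SE. Checkpoint genes fell in 9 of 18 cases and rose in 5 (camera adjusted p = 0.439), MHC class I genes rose in 7 of 17 and fell in 6 (camera adjusted p = 0.421), and B2m rose by 0.23 ± 0.03 SE. Hmox1 changed by -0.55 ± 0.06 SE. Cd274 (0.07 ± 0.14 SE, edgeR adjusted p = 0.686) did not pass and turned negative with library totals. Pancreatic ductal genes rose in 11 of 17 cases and fell in 4 without passing as a list (camera adjusted p = 0.0727), with Muc5ac at 2.66 ± 0.10 SE and Spp1, osteopontin, at -1.27 ± 0.02 SE. Neuronal genes (6 of 13 higher, 5 lower; camera adjusted p = 0.636), histone deacetylases (5 of 15 higher, 4 lower; camera adjusted p = 0.627), acinar genes (1 of 4 higher, 2 lower; camera adjusted p = 0.629) and endothelial markers (1 of 4 higher, 2 lower; camera adjusted p = 0.552) did not pass either. Of the 2 measured MHC class II genes 1 was lower. Of the 2 measured genes of the macrophage and leukocyte list, Cd68 and Fcer1g, 0 changed. Mrc1, a macrophage receptor gene outside that list, went from 66.7 CPM in control to 1.15 CPM with I-BET151.

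ITF2357 against control asked what this histone deacetylase inhibitor changes in these cells. Whether it inhibited the enzymes here is not shown by RNA counts. Lists of mitosis, DNA replication, epithelial, histone, NRF2 and cholesterol synthesis genes rose, and the stress response and RAS-MAPK lists fell. Mki67, a marker of cycling cells, rose from 103 ± 2.69 to 362 ± 7.25 CPM (SD, n = 3; 3.50-fold, edgeR adjusted p = 8.49e-32), and Cdkn1a fell from 15.6 ± 1.33 to 7.64 ± 1.21 CPM (-1.02 ± 0.10 SE; edgeR adjusted p = 1.44e-10). Clca1 rose 12.9-fold to 31.1 ± 1.74 CPM, and Aldh1a1, a retinaldehyde dehydrogenase gene, rose from 4.03 ± 0.588 to 45.7 ± 2.00 CPM (11.3-fold; edgeR adjusted p = 4.25e-26). The further largest rises were those of Cyp2c65 (3.05 ± 0.12 SE), the gastric mucin gene Muc5ac (2.90 ± 0.09 SE), Serpinb1a (2.81 ± 0.09 SE) and Aldh1a7 (2.74 ± 0.14 SE). Cdsn went from 26.9 ± 0.737 to 0.725 ± 0.0339 CPM (-5.20 ± 0.13 SE). The collagen receptor gene Ddr2 (-4.46 ± 0.20 SE), the folate enzyme gene Aldh1l2 (-4.28 ± 0.07 SE), the cysteine synthesis gene Cth (-4.16 ± 0.07 SE), Trib3 (-3.81 ± 0.07 SE), Mmp10 (-3.51 ± 0.16 SE) and Slc7a11 (-3.48 ± 0.05 SE) followed.

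Of 33 mitosis genes 32 rose with ITF2357 and 1 did not pass (median 1.20; camera adjusted p = 1.44e-22), with the kinetochore gene Nuf2 at 2.18 ± 0.10 SE and Hmmr at 1.80 ± 0.07 SE. DNA replication genes rose in 26 of 36 cases, fell in 2 and did not pass in 8 (camera adjusted p = 1.24e-06). Rrm2, a ribonucleotide reductase subunit, rose by 2.18 ± 0.05 SE and cyclin A2 (Ccna2) by 1.92 ± 0.05 SE, while Cdt1 changed by -0.66 ± 0.06 SE. Epithelial genes rose in 15 of 21 cases, with 0 lower and 6 not past the test (camera adjusted p = 2.89e-09), led by Krt20 (1.83 ± 0.04 SE), Muc1 (to 199 ± 6.98 CPM) and Elf3 (1.49 ± 0.07 SE), and Cdh1 rose by 0.87 ± 0.02 SE. Genes of the histone list rose in 13 of 15 cases with 0 lower (camera adjusted p = 4.35e-08), with Hist1h2bc at 1.57 ± 0.06 SE, Hist4h4 at 1.54 ± 0.10 SE and H1f0 at 0.20 ± 0.03 SE. NRF2 and oxidative stress genes rose in 19 of 25 cases and fell in 4 (20 and 4 adjusted over the list alone; camera adjusted p = 1.70e-09), with Gsta1 at 2.22 ± 0.16 SE and Gsta4 at 1.99 ± 0.03 SE against Slc7a11. Cholesterol synthesis genes rose in 20 of 25 cases and fell in 1 (camera adjusted p = 2.72e-06), with Ebp at 0.78 ± 0.06 SE and Idi1 at 0.68 ± 0.07 SE.

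Stress response genes fell in 16 of 24 cases with ITF2357, rose in 5 and did not pass in 3 (median -0.94; camera adjusted p = 1.40e-07). Beside Trib3, Chac1 changed by -2.95 ± 0.09 SE and Ddit3 by -2.56 ± 0.09 SE, and Sdf2l1, an endoplasmic reticulum chaperone partner, rose by 1.08 ± 0.13 SE. RAS-MAPK output genes fell in 19 of 26 cases and rose in 5 (camera adjusted p = 1.77e-06), with the feedback genes Spry4 and Dusp5 at -1.53 ± 0.08 SE and -1.37 ± 0.04 SE and Fos at 0.68 ± 0.06 SE. Glycolysis and hypoxia genes fell in 15 of 27 cases and rose in 7 (camera adjusted p = 0.00134, and adjusted p = 0.0505 with an estimated correlation). Vegfa went from 513 ± 4.80 to 126 ± 3.25 CPM, and Bnip3 changed by -1.01 ± 0.06 SE. MYC and ribosome biogenesis genes fell in 20 of 37 cases and rose in 3 (camera adjusted p = 0.00626, and adjusted p = 0.0799 with an estimated correlation). Myc went to 239 ± 1.17 CPM (-0.72 ± 0.03 SE) and Ptma rose by 0.63 ± 0.03 SE.

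Further lists passed the camera test with ITF2357 but not with an estimated correlation. Pancreatic ductal genes rose in 13 of 17 cases and fell in 3 (camera adjusted p = 0.00557, and adjusted p = 0.0938 with an estimated correlation), with Tff1 at 1.90 ± 0.18 SE and Spp1 at -0.64 ± 0.02 SE. Neuronal genes rose in 8 of 13 cases and fell in 2 (camera adjusted p = 0.00764, and adjusted p = 0.109 with an estimated correlation), with Tubb3 at 2.21 ± 0.15 SE and Map2 at 2.04 ± 0.06 SE. MHC class I genes rose in 8 of 17 cases and fell in 1 (camera adjusted p = 0.0146, and adjusted p = 0.0582 with an estimated correlation). The risen members were led by chaperones that serve glycoproteins in general, Calr (1.06 ± 0.03 SE) and Pdia3 (0.87 ± 0.03 SE), and B2m rose by 0.13 ± 0.03 SE. Mitochondrially encoded genes rose in 8 of 13 cases (camera adjusted p = 6.50e-05, and adjusted p = 0.289 with an estimated correlation), at 3.01% ± 0.1 of counts (SD, n = 3).

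Mesenchymal genes fell in 12 of 22 cases with ITF2357 and rose in 7 without passing as a list (camera adjusted p = 0.0997). Mmp3 changed by -2.32 ± 0.12 SE and Snai2 by -1.59 ± 0.07 SE, while S100a4 rose by 1.34 ± 0.07 SE and Vim by 0.21 ± 0.02 SE. Extracellular matrix genes were divided, with 9 of 24 higher and 9 lower (camera adjusted p = 0.694). Of the fibroblast markers Pdgfra rose by 0.65 ± 0.14 SE, and Pdgfrb and Col1a1 changed by -1.73 ± 0.29 SE and -0.37 ± 0.09 SE. Of the 4 endothelial markers 1 was higher and 1 lower, with Kdr at -2.31 ± 0.23 SE (camera adjusted p = 0.629). Of the 2 macrophage and leukocyte markers Cd68 was lower (-0.70 ± 0.13 SE) and Fcer1g did not pass (edgeR adjusted p = 0.265). Of the 4 acinar genes 1 was higher and 1 lower (camera adjusted p = 0.962), and of the 2 MHC class II genes 1 was higher and 1 lower. Cytokine genes rose in 11 of 25 cases and fell in 6 (camera adjusted p = 0.320), with Vcam1 at 1.73 ± 0.03 SE, Ccl2 at 1.10 ± 0.12 SE and Ptgs2 at -1.50 ± 0.03 SE. Interferon-stimulated genes rose in 12 of 27 cases and fell in 4 (camera adjusted p = 0.296), with Ifit2 at 1.21 ± 0.14 SE. Checkpoint genes rose in 10 of 18 cases and fell in 4 (camera adjusted p = 0.112), with Lgals9 at 1.06 ± 0.03 SE. The log2 fold change of Cd274, ITF2357 vs control, was -0.35 ± 0.14 SE (edgeR adjusted p = 0.0281), a call lost without control replicate 3 (edgeR adjusted p = 0.112), without ITF2357 replicate 1 (0.263) and with DESeq2 (0.0534). Hexim1 rose by 0.71 ± 0.07 SE, Serpini1 by 1.59 ± 0.10 SE and Brd2 by 0.22 ± 0.03 SE, and Hmox1 changed by -0.52 ± 0.06 SE. The BET and P-TEFb list (6 of 13 higher, 6 lower; camera adjusted p = 0.955) and the histone deacetylases (2 of 15 higher, 7 lower; camera adjusted p = 0.384) did not pass. Nor did cyclin-dependent kinase inhibitors and p53 targets (8 of 17 higher, 6 lower; camera adjusted p = 0.911) or apoptosis regulators (9 of 24 higher, 8 lower; camera adjusted p = 0.941). Hdac11 changed by -0.55 ± 0.09 SE and Hdac1 rose by 0.38 ± 0.05 SE.

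The direct comparison of the BET inhibitors, JQ1 against I-BET151 at 1 µM and 48 h, gave 10480 differing genes, 5318 higher and 5162 lower with JQ1, of which 2366 differed by at least 2-fold. Lists of cell cycle, MYC, matrix and cytokine genes were lower and the histone and NRF2 lists higher with I-BET151. Hexim1 was 2.99-fold lower with JQ1 (log2 difference -1.58 ± 0.06 SE; edgeR adjusted p = 6.35e-21), Brd2 differed by -1.08 ± 0.03 SE and Serpini1 by -1.08 ± 0.09 SE. Myc was 2.37-fold higher with JQ1 (1.24 ± 0.03 SE; edgeR adjusted p = 3.32e-28). Clca1, at 1.99 ± 0.457 CPM with JQ1, differed by -6.51 ± 0.08 SE, Muc1 by -3.21 ± 0.03 SE, Muc5ac by -2.88 ± 0.10 SE and Depp1 by -3.80 ± 0.10 SE. Mmp13, at 70.9 ± 1.67 CPM with JQ1, was 97-fold higher than with I-BET151, and Mmp10 differed by 6.41 ± 0.22 SE, Mrc1 by 5.80 ± 0.09 SE and Slc7a11 by 4.74 ± 0.06 SE. Prl2c2 was at least 201-fold lower with I-BET151 than with JQ1.

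By list, 32 of 33 mitosis genes (camera adjusted p = 6.36e-20), 35 of 36 DNA replication genes (camera adjusted p = 2.50e-15) and 31 of 37 MYC and ribosome biogenesis genes (camera adjusted p = 5.43e-10) were higher with JQ1 than with I-BET151. Mesenchymal genes were higher with JQ1 in 20 of 22 cases (camera adjusted p = 1.82e-08), led by Mmp3 (5.22 ± 0.17 SE), and cytokine genes in 20 of 25 (camera adjusted p = 1.13e-06), led by Il1rn (4.23 ± 0.05 SE). Extracellular matrix genes were higher in 18 of 24 cases and lower in 4 (camera adjusted p = 2.51e-07), and cholesterol synthesis genes were higher in 21 of 25 and lower in 2 (camera adjusted p = 6.79e-09). Beside the mesenchymal and matrix genes, the 3 measured fibroblast markers were also higher with JQ1: Col1a1 (1.86 ± 0.11 SE), Pdgfra (1.77 ± 0.17 SE) and Pdgfrb (1.11 ± 0.26 SE). Of the 4 endothelial markers 2 were higher and 0 lower, with Kdr at 2.46 ± 0.27 SE. Glycolysis and hypoxia genes were higher in 20 of 27 cases (camera adjusted p = 6.79e-09), RAS-MAPK genes in 19 of 26 (camera adjusted p = 4.22e-05) and stress response genes in 14 of 24 (camera adjusted p = 0.00205). Histone genes were lower with JQ1 in 11 of 15 cases (camera adjusted p = 0.000130) and NRF2 genes in 18 of 25 (camera adjusted p = 3.17e-06). Epithelial genes were lower in 12 of 21 cases and higher in 5 (camera adjusted p = 0.000489, and adjusted p = 0.0642 with an estimated correlation), and BET and P-TEFb genes lower in 8 of 13 (camera adjusted p = 0.0331, and adjusted p = 0.127 with an estimated correlation). Mitochondrially encoded genes were lower in 11 of 13 cases (camera adjusted p = 8.69e-07, and adjusted p = 0.187 with an estimated correlation).

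No difference between the BET inhibitors was found for B2m (-0.02, 95% interval -0.09 to 0.04; edgeR adjusted p = 0.475). The log2 fold change of B2m, JQ1 vs I-BET151, turned to 0.13 and passed with library totals (edgeR adjusted p = 0.000105). Cd274 was higher with JQ1 by 0.47 ± 0.13 SE (edgeR adjusted p = 0.00214), Vim by 0.54 ± 0.02 SE, Ccl2 by 2.46 ± 0.16 SE and Hmox1 by 0.25 ± 0.06 SE. Cdh1 differed by -0.67 ± 0.02 SE and H1f0 by -0.82 ± 0.03 SE. The log2 fold change of Cdkn1a, JQ1 vs I-BET151, was 0.29 ± 0.10 SE (edgeR adjusted p = 0.0131), a call lost without JQ1 replicate 2 (edgeR adjusted p = 0.0768) or I-BET151 replicate 2 (0.0546). Differences higher with JQ1 made up 50.7% of these calls with TMM factors and 68.9% with library totals, which moved the median of all genes by 0.15. The median of the BET and P-TEFb list, -0.11, lay within that shift.

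ITF2357 and JQ1 differed in 8421 genes, 4404 higher and 4017 lower with ITF2357, and 1100 by at least 2-fold. Cell cycle, epithelial and NRF2 genes were higher with ITF2357, and hypoxia, RAS-MAPK, mesenchymal and stress response genes lower. Clca1 was 15.3-fold higher with ITF2357 (edgeR adjusted p = 1.66e-26), Muc5ac differed by 3.11 ± 0.09 SE, Cyp2c65 by 2.83 ± 0.11 SE, Aldh1a1 by 2.77 ± 0.08 SE and Fam83b by 2.40 ± 0.15 SE. Mmp10 differed by -3.99 ± 0.15 SE, Ddr2 by -3.78 ± 0.21 SE, Aldh1l2 by -3.31 ± 0.07 SE, Grem1 by -2.99 ± 0.15 SE and Mmp13 by -2.95 ± 0.07 SE. Higher with ITF2357 were 32 of 33 mitosis genes (camera adjusted p = 2.10e-25), 30 of 36 DNA replication genes (camera adjusted p = 3.03e-11), 15 of 21 epithelial genes (camera adjusted p = 2.89e-09), 21 of 25 NRF2 genes (camera adjusted p = 3.29e-12) and 12 of 15 histone genes (camera adjusted p = 1.00e-06). Lower were 21 of 27 glycolysis and hypoxia genes (camera adjusted p = 2.83e-11), 20 of 26 RAS-MAPK genes (camera adjusted p = 2.89e-09), 15 of 24 stress response genes (camera adjusted p = 2.24e-06), 15 of 22 mesenchymal genes (camera adjusted p = 0.000198) and 15 of 24 matrix genes (camera adjusted p = 0.000863). Of the 3 fibroblast markers 2 were lower and 1 higher. MHC class I genes were higher in 6 of 17 cases and lower in 1 (camera adjusted p = 0.00906), and cholesterol genes did not differ as a list (camera adjusted p = 0.997). Calls lost with an estimated correlation were those of the MYC list (17 of 37 higher; camera adjusted p = 0.00723, and adjusted p = 0.0839 with an estimated correlation), the ductal list (11 of 17 higher; camera adjusted p = 0.00205, and adjusted p = 0.0709 with an estimated correlation) and the neuronal list (7 of 13 higher; camera adjusted p = 0.0337, and adjusted p = 0.182 with an estimated correlation). Myc differed by -0.40 ± 0.03 SE, Cdkn1a by -0.79 ± 0.10 SE and Cd274 by -0.89 ± 0.13 SE, and Hexim1 was higher by 0.47 ± 0.07 SE. H1f0 did not differ (0.02 ± 0.03 SE; edgeR adjusted p = 0.571). Genes higher with ITF2357 made up 52.3% of calls with TMM factors and 41.8% with upper-quartile factors.

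ITF2357 and I-BET151 differed in 10896 genes, 5531 higher and 5365 lower with ITF2357, and 2425 by at least 2-fold. The cell cycle lists lay furthest apart here: all 33 mitosis genes (median 2.59; camera adjusted p = 1.09e-27) and all 36 DNA replication genes (median 1.47; camera adjusted p = 2.44e-21) were higher with ITF2357. Mki67 was 6.35-fold higher (edgeR adjusted p = 9.63e-36), Ube2c differed by 3.12 ± 0.07 SE and Ccna2 by 2.84 ± 0.06 SE. Higher with ITF2357 were also Ccl9 (5.73 ± 0.19 SE), Sprr1a (5.67 ± 0.08 SE), Klra4 (5.40 ± 0.26 SE), Mrc1 (5.28 ± 0.10 SE), Fgf2 (5.28 ± 0.21 SE) and Tmigd1 (5.24 ± 0.17 SE), and Prl2c2 was at least 140-fold lower with I-BET151. Lower with ITF2357 were Depp1 (-2.79 ± 0.09 SE), Clca1 (-2.58 ± 0.05 SE), Wnt4 (-2.18 ± 0.09 SE), Gpr146 (-2.17 ± 0.10 SE) and Muc1 (-1.93 ± 0.03 SE). Higher as lists were MYC and ribosome biogenesis (35 of 37; camera adjusted p = 1.74e-14), cholesterol synthesis (21 of 25; camera adjusted p = 1.94e-09), cytokine (18 of 25; camera adjusted p = 3.96e-05), matrix (18 of 24; camera adjusted p = 2.02e-05) and mesenchymal genes (12 of 22; camera adjusted p = 0.00293). Of the 3 fibroblast markers 2 were higher and 1 lower. Calls lost with an estimated correlation were those of the checkpoint (12 of 18 higher; camera adjusted p = 0.0447, and adjusted p = 0.0865 with an estimated correlation), neuronal (8 of 13 higher; camera adjusted p = 0.0401, and adjusted p = 0.195 with an estimated correlation), BET and P-TEFb (7 of 13 lower; camera adjusted p = 0.00606, and adjusted p = 0.0668 with an estimated correlation) and mitochondrially encoded lists (12 of 13 lower; camera adjusted p = 4.18e-07, and adjusted p = 0.177 with an estimated correlation). Serpini1 (-0.16 ± 0.08 SE, edgeR adjusted p = 0.0941) and Hmox1 (0.04 ± 0.06 SE, edgeR adjusted p = 0.623) did not pass. Genes higher with ITF2357 made up 50.8% of calls with TMM factors and 65.5% with library totals, and the log2 fold change of Cdh1, ITF2357 vs I-BET151, turned from -0.07 ± 0.02 SE to 0.07 with library totals.

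Genes changed by more than 1 compound went mostly the same way. JQ1 and I-BET151 shared 1502 rises and 1592 falls, where independent lists of these sizes would share 665 and 694, and 596 of 3690 genes changed by both (16.2%, 95% interval 15.0 to 17.4) went in opposite directions. JQ1 and ITF2357 shared 1507 rises and 1451 falls (600 and 562 for independent lists), with 13.3% in opposite directions. I-BET151 and ITF2357 shared 2700 rises and 2614 falls (1462 and 1489 for independent lists), with 24.8% in opposite directions. All 3 compounds raised 1162 genes and lowered 1149, against 183 of each for independent lists. Genes with more counts pass more easily in every comparison, so unrelated changes could also share more genes than independent lists do. Among the genes lowered by all 3 were 13 of the 24 stress response genes, including Trib3, Asns, Ddit3, Chac1 and Atf4. Simulated unchanged groups, set against simulated controls in common, shared at most 1 gene in either direction. Few genes pass in such groups, so this does not show how many shared calls come from the controls. The log2 fold changes of JQ1 and I-BET151 correlated across 8129 genes with r = 0.512, and unchanged groups gave a mean of 0.507 from the shared controls alone. Such a simulated r follows from the sharing itself, however small the noise, so it is no measure of how alike the compounds are. The covariance of JQ1 and I-BET151 was 0.0606 against 0.00161 in simulations. For JQ1 and ITF2357 r was 0.590 (0.518 simulated) with a covariance of 0.0469 (0.00160 simulated), and for I-BET151 and ITF2357 r was 0.539 (0.513 simulated) with a covariance of 0.154 (0.00162 simulated). In each pair the simulated covariance was far below the observed one, so independent noise in the controls gave little of it. A state that the control libraries share was not simulated. The 3 control libraries could not be split into separate sets of 2, so part of the shared calls may come from the shared controls. The control is described as untreated and as receiving PBS, and no solvent of the compounds is named. An effect of a solvent given only with the compounds therefore cannot be told apart from a change shared by all 3.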

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

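The quasi-likelihood test, the likelihood ratio test, DESeq2, the other scalings, the filters, the replicate block, the fit to protein-coding genes (chosen after seeing the data) and the fit to only the 2 groups compared kept each count of changed genes within 1.5 times its main value. DESeq2 gave 3921, 10417 and 8764 changed genes for JQ1, I-BET151 and ITF2357 against control. Without 1 library, which leaves 2 in its group, there were 3457 to 3719 genes changed, JQ1 vs control, 10246 to 10367 genes changed, I-BET151 vs control, and 8619 to 9124 genes changed, ITF2357 vs control. There were 9749 to 9937 genes changed, JQ1 vs I-BET151, 7601 to 8220 genes changed, ITF2357 vs JQ1, and 10150 to 10551 genes changed, ITF2357 vs I-BET151. Each of these was below the count with all libraries, as fewer libraries were used. At 2-fold or more, 105, 2729, 1501, 2366, 1100 and 2425 genes were left in the 6 comparisons, and the shared calls fell to 23 higher and 36 lower for JQ1 and I-BET151, 26 and 27 for JQ1 and ITF2357, and 241 higher and 405 in the overlap of calls between compounds, I-BET151 and ITF2357, both lower. These are smaller by construction. Running without a filter changed no value, since the filter removed 0 genes.

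Rises made up 52.9% of the calls with RLE size factors, 58.7% with upper-quartile factors and 48.1% with library totals for JQ1 vs control. The shares were 45.9% (upper quartile) and 33% (totals) for I-BET151 vs control, and 52.4%, 46% and 47.5% (RLE, upper quartile and totals) for ITF2357 vs control. They were 56.3% and 68.9% (upper quartile and totals) for JQ1 vs I-BET151, 41.8% and 48.9% for ITF2357 vs JQ1, and 49.7% and 65.5% for ITF2357 vs I-BET151. With library totals 62 of 9367 genes called in both fits for I-BET151 vs control had opposite signs. So had 52 of 8658 for JQ1 vs I-BET151 and 15 of 9275 for ITF2357 vs I-BET151. The cause was not tested.

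Of 25 lists, camera with an estimated correlation called 8 for JQ1, 8 for ITF2357 and 7 for ITF2357 vs I-BET151. Fry called 21, 25 and 22 against control, 24 for JQ1 vs I-BET151 and 23 for ITF2357 vs I-BET151, and it compares a list with no other genes. The direction turned with fry for apoptosis regulators with ITF2357 (fry adjusted p = 0.668), REST-repressed neuronal genes in JQ1 vs I-BET151 (fry adjusted p = 0.711), cholesterol synthesis in ITF2357 vs JQ1 (fry adjusted p = 0.316) and RAS-MAPK genes in ITF2357 vs I-BET151 (fry adjusted p = 0.000183). Cholesterol synthesis in ITF2357 vs JQ1 also turned with the replicate block (camera adjusted p = 0.969). The cause was not tested.

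Of 10067 alternative values of the named genes 9933 kept direction and side of the threshold, 119 lost the call, 4 gained it and 11 turned. The 635 values without a filter are among those kept and were the same by construction. Many of the genes were also named for large changes in these data, which favours agreement. With library totals Cd274 (-0.093) turned in I-BET151 vs control, B2m (0.13) in JQ1 vs I-BET151, and B2m (0.031) and Cdh1 (0.069) in ITF2357 vs I-BET151. B2m also turned in JQ1 vs I-BET151 with upper-quartile factors (0.023) and the stricter filter (0.015), and H1f0 in ITF2357 vs JQ1 with upper-quartile factors (-0.038), the stricter filter (-0.006) and protein-coding genes only (-0.02). Without 1 library, the log2 fold change of Fcer1g, I-BET151 vs control, ranged from -0.464 to 0.074. The cause was not tested.

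Replicates share only a number in the labels. With replicate number as a block 4141, 10865, 9247, 10361, 8251 and 10764 genes changed. Only 2 of 12 libraries were best matched by their own number, and correlations of residuals ran from -0.217 to 0.145, with 0 of 6 pairs of groups over 0.1 in every number.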

Other observations

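The gene families in this part were chosen after their values were seen. Histone genes picked by name, most of them from the histone clusters, rose almost without exception with ITF2357: 62 of 65 were higher, 0 lower and 3 did not pass, with a median of 1.20 (1.17 to 1.21 under the other scalings). With I-BET151 25 were higher and 27 lower, and with JQ1 9 were higher and 3 lower. Of these genes 11 also stood among the 15 measured genes of the fixed histone list, so its result is in part the same, and counts of such close paralogs are uncertain. Glutathione transferase genes rose in 10 of 10 cases with ITF2357 (median 1.62), with Gstm1 at 1.75 ± 0.04 SE and Gsta4 at 1.99 ± 0.03 SE, and in 4 of 10 with I-BET151, where 3 fell.

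The 4 measured mucin genes rose with I-BET151 (median 2.61) and with ITF2357 (median 1.54), and 3 of 4 rose with JQ1. The 5 Clca genes rose with ITF2357, with Clca3b at 2.26 ± 0.13 SE and Clca4a at 1.57 ± 0.31 SE, whereas with I-BET151 3 rose and Clca3a1 changed by -0.48 ± 0.05 SE. Serpin B genes rose in 7 of 8 cases with ITF2357, and Serpinb5, maspin, went to 2.63 ± 0.23 SE with ITF2357 and -2.54 ± 0.45 SE with I-BET151. Of 11 matrix metalloproteinase genes 7 fell and 3 rose with I-BET151, with Mmp15 at 2.57 ± 0.05 SE. Among long non-coding RNAs 136 of 1520 were higher and 388 lower with ITF2357, 315 and 382 with I-BET151 and 47 and 77 with JQ1. Genes annotated to other non-coding classes also leaned lower with ITF2357. Of 107 miRNA genes 3 were higher and 23 lower, and of 106 snRNA genes 4 were higher and 19 lower. Whether reads at miRNA, snRNA or snoRNA genes came from the small RNA or from a longer transcript was not tested. Of 12665 protein-coding genes 4402 were higher and 3554 lower with ITF2357, and of 1369 processed pseudogenes 140 and 111. Of 137 snoRNA genes 1 was higher and 32 lower with ITF2357 (median -0.43). These numbers were 1 and 40 with I-BET151 (median -0.45) and 0 and 3 with JQ1. Over the libraries of a group, Try5 had 42 counts in control, 4 with JQ1, 10 with I-BET151 and 12 with ITF2357, and H2-DMb1 had 47, 47, 5 and 149.

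For the smaller response to JQ1, the tests of a mixture and of a mislabelled library were chosen only after the result was seen. JQ1 changed 4308 genes and I-BET151 10945, and 3 technical explanations were tested. If JQ1 libraries held control RNA with some I-BET151 RNA, shared genes would go the same way, but 16.2% of them went in opposite directions. With each library thinned to the lowest total the ratio of changed genes was still 2.59. The highest correlation of a JQ1 with a control library was 0.9907, below the lowest of 0.9921 between control libraries and 0.9928 between JQ1 libraries. A lower effective dose or activity of JQ1 in these cultures could also give a smaller response and was not tested.

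For the stress response genes lower with each compound, both tests were chosen only after the result was seen. If the state of the control libraries were the whole cause of every fall, the list would not differ between compounds. Its median was -0.587 in ITF2357 vs JQ1 (camera adjusted p = 2.24e-06), which speaks only to the further fall with ITF2357. The fall already seen with JQ1 (median -0.331) could still come wholly from the control state. For chance from the shared controls, 13 of 24 list genes had a negative sign in all 3 comparisons, and simulated unchanged groups gave up to 11. Called lower in all 3 were 13 genes here and at most 0 in those groups. Few genes pass in unchanged groups by the threshold itself, so these calls do not decide whether sampling noise was the whole cause. The simulated noise was independent between libraries, so it cannot show a state that the control libraries share. The 3 control libraries could not be split between the comparisons. An effect of the control state, or of a solvent given only with the compounds, therefore cannot be told apart from a shared fall.

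For the mitosis and DNA replication genes, higher with ITF2357 and lower with I-BET151, the test of scaling was chosen only after the result was seen. For a trend with gene length or expression level, the 95th percentile of matched lists reached at most 37% of a list's own median. For library scaling, the largest shift of a median was 15.7%. Each of these scalings is relative to the counts of a library, so none can show a change in total RNA per cell. Cell density or the state of the medium at 48 h could also change these genes and was not tested.

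Whether other groupings of the libraries call as many genes was examined with the 10 splits of the 6 libraries of each comparison, which are too few for a share under 0.1. In each comparison 1 of 10 splits, the real one, gave as many genes changed. In JQ1 vs control it gave 4308 and the highest other split 1, and in the other comparisons the highest other split gave 0.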
